A study of Mus musculus with 13 samples.

How the data were processed

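Per the labels, total RNA from ventral tegmental area punches was purified with RNeasy Micro columns and made into ribosomal-RNA-depleted TruSeq libraries. Per the submitters' processing notes, reads were aligned with Bowtie2 to GRCm39, counted with featureCounts and compared with DESeq2, without versions. The authors deposited 1 table of signal, which is counts divided by DESeq2 size factors, for 26264 genes in 13 samples, and that table was used here. Reads were not realigned, and the fastq data were not used here.

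Within each sample the values are multiples of a single step, so whole reads were recovered by dividing by it. All 341432 values (100%) lay within 0.01 of a whole read. The recovered reads per sample and the normalized totals, 34.6 to 37.0 mega-counts, served as checks of depth and scaling. Ribosomal precursor Rn45s held 2.16 to 4.68% of reads. Replicates of a group correlated at 0.971 to 0.984, with chi-square per degree of freedom of 16.2 to 51.5.

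Genes were tested when at least 2 samples reached 10 normalized counts: 17755 were kept, 8509 dropped, and 3670 of the dropped were 0 everywhere. The test was limma 3.58.1 with a trend (R 4.3.3) on log2 of the normalized count plus 1, with 4 group means and a term for sex, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 for adjusted p. The prior degrees of freedom were 4.64. Comparisons were the effect of Setd7 without and after defeat, of defeat with GFP and with Setd7, their interaction, both together, each averaged over the other, sex, and the difference of the Setd7 effect between sexes. The choice of test, comparisons, filter, gene lists, naming rule and most alternatives was made before the data were examined.

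Lists of genes were written from general knowledge: dopamine neurons, GABA neurons, excitatory neurons, neighbouring nuclei, oligodendrocytes, their precursors, astrocytes, microglia, endothelial and mural cells, meningeal fibroblasts, choroid plexus, blood, immediate early genes, glucocorticoid response, histone H3 lysine 4 methylation, other chromatin regulators, interferon and antigen presentation, reactive glia, neurotransmitter receptors, ion channels, synaptic genes, neuropeptides, oxidative phosphorylation, ribosomal proteins, heat shock and folding, circadian clock, perineuronal nets, p53 targets and mitochondrially encoded genes. Of 29 lists 28 were tested, and the mitochondrially encoded list is not analysed here because 0 of its 13 members are in the table. Lists were tested with camera with a preset correlation of 0.01, again with the correlation estimated from the residuals, and with fry, each adjusted over the lists of a comparison. A list call by camera with the preset correlation is the planned one. The planned call was lost for all 93 list calls when the correlation was estimated, and for 91 of them with fry. Examples for a list are its members with the smallest unadjusted p. The results of 3 genes are not reported here.

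Genes were named by rule: Setd7, then up to 10 passing genes per direction with the largest change, and where fewer than 5 passed, the 5 with the smallest unadjusted p. Named genes needed a mean of 30 normalized counts in the groups compared. Predicted and RIKEN names were left out, and Xist, Tsix and Y genes were named only with sex.

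Count tests on the recovered reads were edgeR 4.0.16 and DESeq2 1.42.0 with the same design. They called 0 and 35 genes for Setd7 without defeat, 0 and 85 for defeat with GFP, 0 and 6 for Setd7 after defeat, 0 and 7 for defeat with Setd7, 0 and 1 for the interaction, 0 and 26 for both together, 1 and 7 for the averaged Setd7 effect, and 0 and 8 for the averaged defeat effect. DESeq2 set the adjusted p aside by independent filtering for 6540, 3443 and 1033 genes in the first, second and combined comparison. Genes called by both limma and DESeq2 were 11 for sex and 1 for the averaged Setd7 effect.

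Changes of known size were put into simulated data made from the samples to see how many the test recovers. Counts were drawn for each gene independently, so shifts that many genes of a library share, such as tissue content, are absent. The shares recovered need not hold for the real data, where Setd7 itself, 5.80-fold higher without defeat, had adjusted p = 0.467 by limma. For Setd7 without defeat it called 31.3, 62.7 and 86.4% of genes changed 1.5, 2 and 4-fold with 5 false calls. Defeat with GFP gave 49.3, 62.7 and 83.3% with 4 false calls, Setd7 after defeat 34.3, 64.2 and 83.3% with 6, defeat with Setd7 32.8, 61.2 and 78.8% with 13, both together 19.4, 55.2 and 75.8% with 3, and the averaged Setd7 effect 56.7, 79.1 and 89.4% with 12.

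Gene names were matched to a reference of the previous mouse build (GRCm38), by name only and without coordinates, because the table was made on GRCm39. 26213 of 26264 names matched. Lists of regional markers (thalamus, pons and hindbrain, cortex and hippocampus, hypothalamus, tectum, pituitary) were written after Slc17a7, Tcf7l2 and Lhx9 had been seen, and pituitary, with 2 genes tested, was not used as a list. Leaving out the 3 libraries with low dopamine neuron genes and the 2 with high interferon genes are alternatives chosen after the data had been seen. Agreement between comparisons was set against 100 datasets in which the residuals of the fit were permuted over samples.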

Results

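The data describe gene expression in tissue punches of the mouse ventral tegmental area (VTA), the midbrain region whose dopamine neurons project to the striatum and cortex. Animals of both sexes received a virus carrying Setd7 or green fluorescent protein (GFP) at postnatal day 14, and some met social defeat stress as adults. Setd7 is a lysine methyltransferase able to monomethylate lysine 4 of histone H3. The 4 groups are named GFP control (n = 3, 1 female), GFP defeat (n = 4, 2 female), Setd7 control (n = 4, 2 female) and Setd7 defeat (n = 2, 1 female), where control means without defeat. Total RNA was sequenced in 13 libraries, 7 male and 6 female. Reads assigned to genes (in Mreads, mega-reads) were, in replicate order, 26.5, 50.8 and 33.4 in GFP control and 48.1, 35.6, 30.9 and 36.3 in GFP defeat. They were 33.8, 48.4, 33.1 and 35.6 in Setd7 control and 35.3 and 31.2 in Setd7 defeat. Of 26264 genes, 17755 were tested. Values are normalized counts with standard deviation (SD) or log2 fold changes ± standard error (SE), and all tests are two-sided. The labels do not say that every library is a separate animal, so the p-values measure spread between samples. The number naming Setd7 defeat replicate 1 is longer in its data column than in its title, so whether this library holds 1 animal is not settled.

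The first question was whether the virus raised Setd7. Setd7 read 14538, 13480.5 and 13664 in GFP control, 10888, 14060, 12946 and 12799 in GFP defeat, 158681, 140236, 81302 and 28587 in Setd7 control, and 92287.5 and 123133 in Setd7 defeat. Setd7 means ± SD were 13894 ± 565 (n = 3), 12673 ± 1317 (n = 4), 102201 ± 59139 (n = 4) and 107710 ± 21811 (n = 2), which is 7.36-fold above GFP without defeat and 8.50-fold after it. Every Setd7 library lay above every GFP library (log2 difference 2.80, exact permutation p = 0.000583, 1 of 1716 splits and the smallest p possible), and the lowest, Setd7 control replicate 4, held 2.17 times the mean of all GFP libraries. Setd7 rose in the effect averaged over defeat, by 2.81 ± 0.30 (adjusted p = 0.00861 by limma), but its adjusted p was 0.0658 (log2 fold change 2.54) without Setd7 defeat replicate 2, 0.632 with robust fitting (at the same 2.81), 0.0659 (2.88) with a dopamine neuron covariate and 0.190 (2.89) without 3 libraries low in dopamine neuron genes. In the single comparisons Setd7 was higher by 2.54 ± 0.40 without defeat (adjusted p = 0.467 by limma, 0.435 by edgeR, 1.2e-05 by DESeq2) and by 3.08 ± 0.45 after defeat (0.236 by limma, 0.0844 by edgeR, 1.15e-05 by DESeq2). Leaving out Setd7 control replicate 4 gave Setd7 3.09 (adjusted p = 6.92e-05) and 3.08 (adjusted p = 0.000101) by limma. Defeat left Setd7 at −0.21 ± 0.40 with GFP (adjusted p = 0.914) and 0.33 ± 0.45 with Setd7 virus (adjusted p = 0.9999).

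**Figure D1:**
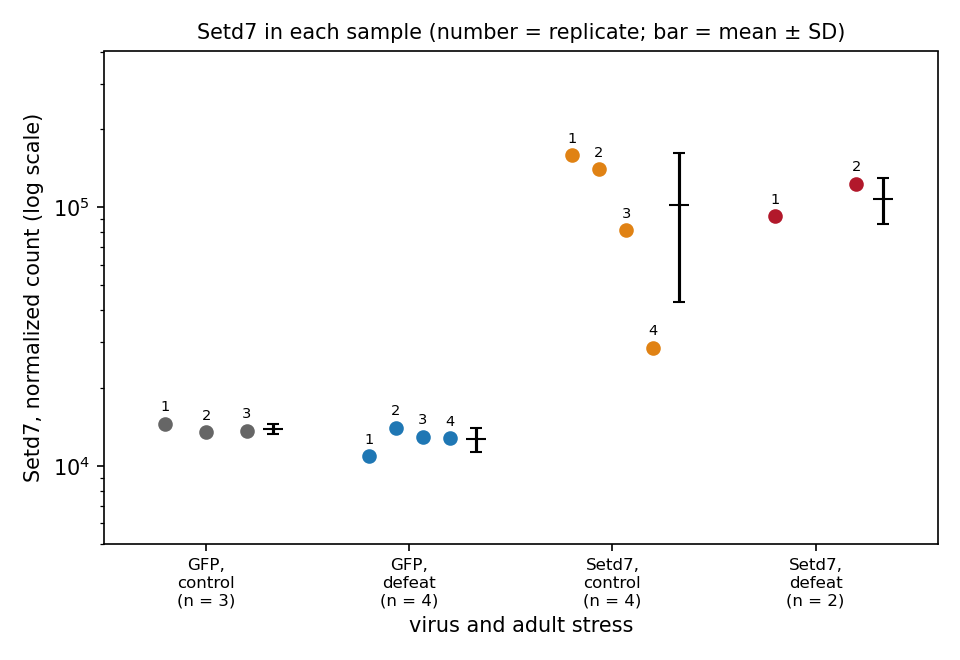
Setd7 normalized counts on a logarithmic vertical axis for the 4 groups, where each point is a library with its replicate number and bars show mean ± SD. Setd7 control replicate 4 is the low point at 28587.

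The first comparison asked what Setd7 does to the VTA of mice that met no defeat (Setd7 control, n = 4, against GFP control, n = 3). Genes marking dopamine neurons were higher with Setd7: 26 of 28 members lay above GFP control, with a median log2 fold change of 0.87 (camera adjusted p = 9.34e-13, 0.438 with an estimated correlation). Ntsr1, the neurotensin receptor of these neurons, was higher by 1.24 ± 0.33, the forkhead factor Foxa1 by 1.25 ± 0.33 and Klhl1 by 0.61 ± 0.17. These 3 members pass when adjusted over the list alone, 0 over all genes. Th, which makes the dopamine precursor, averaged 5220 ± 3956 in GFP control and 13235 ± 4187 in Setd7 control (1.58 ± 0.57, adjusted p = 0.579). In the GFP groups Th read 3392, 2508 and 2539 in GFP control replicates 2 and 3 and GFP defeat replicate 1, against 9760 to 19111 in every other library. Without those 3 libraries the dopamine median was 0.10 (adjusted p = 0.727), and averaged over defeat it was 0.00 (0.915). Here and wherever these 3 are left out, GFP control is replicate 1 alone (n = 1), which limma takes to vary like the other groups.

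Genes of the thalamus, which lies above the midbrain, went the other way: 11 of 11 markers chosen after the data were seen were lower with Setd7, with a median of −0.97 (adjusted p = 8.05e-06, 0.3999 with an estimated correlation). The mean thalamus value was 8.60, 11.39 and 9.52 in GFP control replicates 1, 2 and 3, against 8.07 to 8.94 in Setd7 control. Tcf7l2, a factor of thalamic neurons, read 1869, 9009 and 9559 in the 3 GFP control libraries, 6575 in GFP defeat replicate 4 and 949 to 1449 in the other 9 (−2.21 ± 0.47). Markers of excitatory neurons had a median of −0.25 (12 of 16 lower, adjusted p = 0.0582), and 2 pass when adjusted over the list alone, the vesicular glutamate transporters Slc17a7 (−3.36 ± 0.89) and Slc17a8 (−2.56 ± 0.73). Slc17a7 read 211, 1823 and 5064 in the 3 GFP control libraries and 97.9 to 251 in all Setd7 libraries. The median of tectum markers was −0.55 (adjusted p = 0.176), of cortex and hippocampus −0.38 (0.176), of pons and hindbrain −0.62 (0.764) and of hypothalamus 0.56 (0.246).

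Cytosolic ribosomal protein genes were higher with Setd7 in 40 of 43 members, with a median of 0.21 (adjusted p = 9.34e-13, 0.111 with an estimated correlation, fry adjusted p = 0.0280). Examples are Rpl4 (0.25 ± 0.06), Rps9 (0.36 ± 0.10) and Rpl32 (0.56 ± 0.16), whose reads are shared with many processed copies and so are uncertain gene by gene. Heat shock and protein folding genes were higher in 21 of 24 (0.21, adjusted p = 3.65e-08, 0.195 with an estimated correlation). Among them were the chaperone Hsp90ab1 (0.22 ± 0.06), Dnajb1 (0.27 ± 0.08) and mitochondrial Hspd1 (0.22 ± 0.07). Nuclear genes of oxidative phosphorylation were higher in 35 of 36 (0.12, adjusted p = 1.95e-07, 0.596 with an estimated correlation), as in Ndufa2 (0.43 ± 0.16) and Ndufa1 (0.33 ± 0.13), but without GFP control replicate 1 their median was 0.04 (adjusted p = 0.286). Circadian clock genes were lower in 18 of 20 (−0.21, adjusted p = 5.36e-08, 0.195 with an estimated correlation). Bhlhe40 (−0.32 ± 0.09) and Nr1d1 (−0.39 ± 0.11), both repressors in the clock loop, pass when adjusted over the list alone. Leaving out the 3 libraries with low Th left 1 GFP control library to compare with, against which the medians were −0.05 (adjusted p = 0.727) for clock, 0.26 (7.70e-08) for ribosomal and 0.23 (2.36e-06) for heat shock genes.

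Interferon and antigen presentation genes were higher with Setd7 in 25 of 26 (0.68, adjusted p = 0.000195, 0.712 with an estimated correlation), led by Ifit2 (0.36 ± 0.19), Psmb9 (1.33 ± 0.73) and Tap1 (1.21 ± 0.71). Setd7 control replicate 4 stood apart, with a mean of 10.10 against 6.95 to 7.14 in its group and 8725 counts of Cd74, which accompanies MHC class II. Without it the interferon median was −0.10 (adjusted p = 0.247). Microglia genes were higher in 18 of 20 (0.35, adjusted p = 0.0126, 0.769 with an estimated correlation), for example Tmem119 (0.44 ± 0.25) and C1qa (0.70 ± 0.43). Without the same library the microglia median was −0.09 (0.286), and without GFP control replicate 2 or 3 it was 0.22 (0.152) or 0.28 (0.104). Oligodendrocyte genes were higher in 18 of 20 (0.15, adjusted p = 0.00134, 0.627 with an estimated correlation), with Trf at 0.19 ± 0.09 and Mal at 0.17 ± 0.09, and had a median of 0.08 (0.208) without GFP control replicate 2. Neurotransmitter receptor genes were lower in 22 of 28 (−0.07, adjusted p = 0.0369, 0.627 with an estimated correlation; Grm5 −0.22 ± 0.08, Gria2 −0.19 ± 0.09). Ion channel genes were lower in 24 of 30 (−0.10, adjusted p = 0.0369, 0.438 with an estimated correlation; Cacna1g −0.39 ± 0.15, Kcnj3 −0.40 ± 0.17). The receptor and channel calls end without GFP control replicate 2, at −0.03 (0.856) for receptors and −0.10 (0.168) for ion channels, and without Setd7 control replicate 3 (−0.04, 0.0985 and −0.07, 0.0985) or 4 (−0.05, 0.136 and −0.08, 0.180). The receptor call also ends without Setd7 control replicate 1 (−0.07, 0.0605), and the channel call without GFP control replicate 3 (−0.04, 0.133) or GFP defeat replicate 4 (−0.10, 0.0558). With the 3 libraries with low Th left out, all 5 calls of this paragraph end: interferon 0.25 (0.615), microglia 0.00 (0.812), oligodendrocyte −0.01 (0.949), receptors −0.07 (0.727) and ion channels −0.01 (0.812).

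Over single genes, limma called 0 in the effect of Setd7 without defeat (1423 at unadjusted p under 0.05, 766 higher and 657 lower, where 887.75 are expected by chance), edgeR 0 and DESeq2 35. Beside Setd7, the higher genes named by rule were Magee2 (364 ± 61.9 against 556 ± 41.1, 0.58 ± 0.10), Tspyl3 (1129 ± 75.1 against 1456 ± 72.6) and the adhesion receptor Adgra3 (903 ± 15.5 against 1173 ± 41.8). With the secreted Wnt modulator Dkk3 (2295 ± 303 against 3390 ± 359) and Plpp2 (224 ± 24.5 against 370 ± 34.99) they all had adjusted p = 0.467 by limma. Lower were Wdr90 (328 ± 23.4 against 181 ± 22.9, −0.88 ± 0.17), Ttc14 (3559 ± 84.4 against 2620 ± 191) and Mir124a-1hg, a host transcript of the neuronal microRNA miR-124 (2469 ± 270 against 1307 ± 412, −0.91 ± 0.18, adjusted p = 0.470). Cttnbp2 (−0.47 ± 0.10) and Peak1 (−0.39 ± 0.08, adjusted p = 0.539) followed. Without the 3 libraries with low Th the value of Cttnbp2 was −0.29. DESeq2 called Magee2 (adjusted p = 0.00156), Mir124a-1hg (0.00317), Dkk3 (0.0041) and Slc17a7 (0.00438) among its 35.

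**Figure D2:**
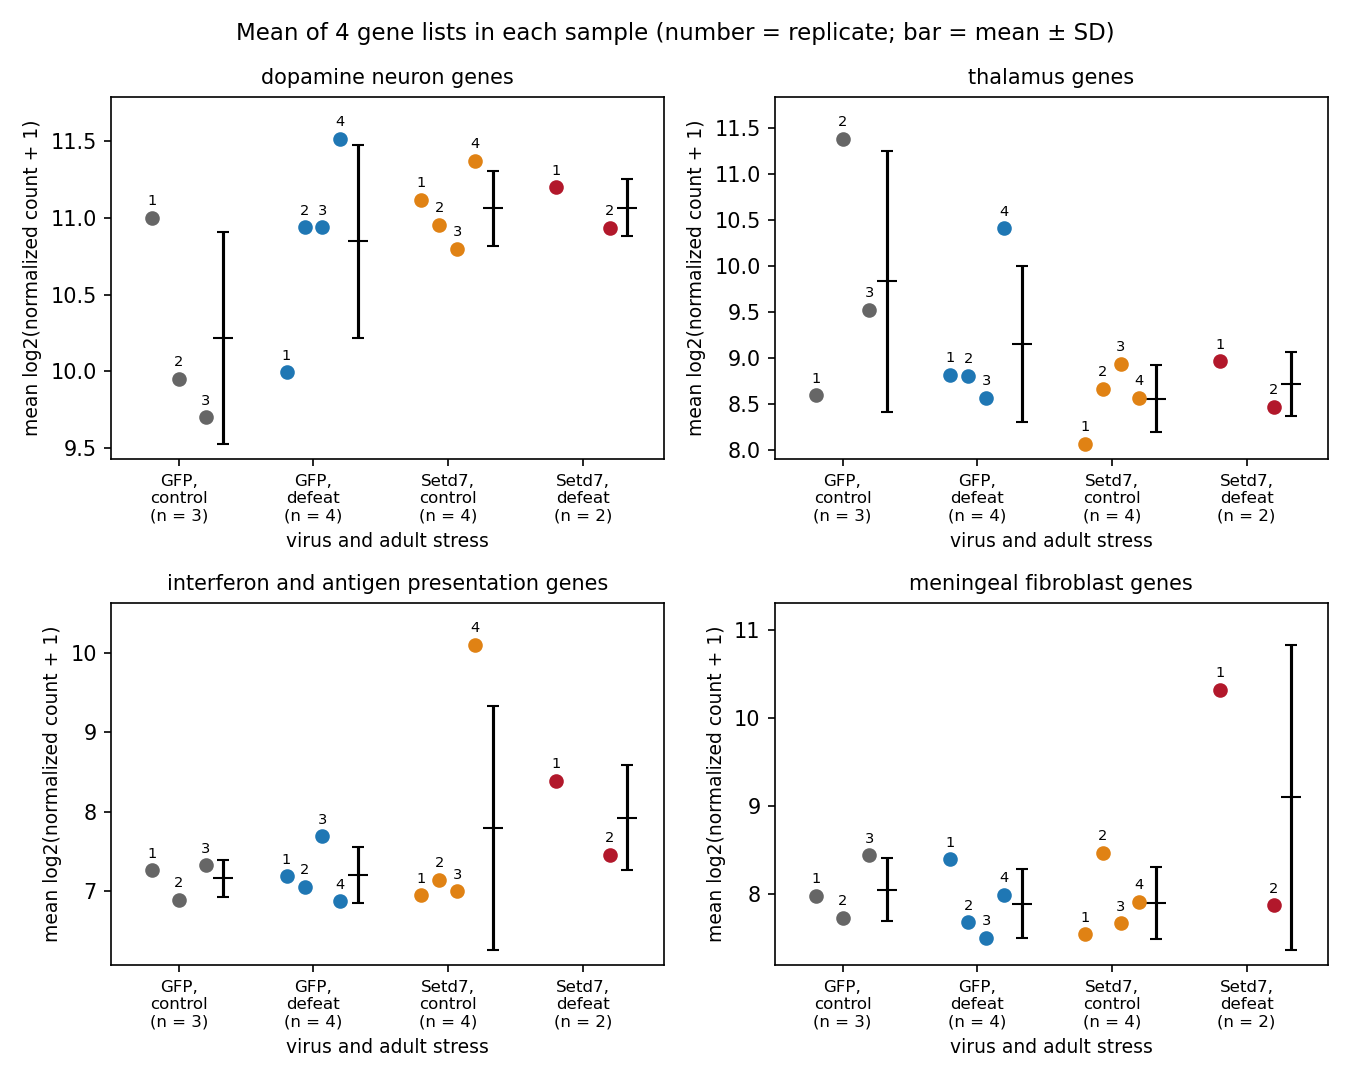
Mean log2 normalized count per library for genes of dopamine neurons, thalamus, interferon response and meninges, with groups on the horizontal axis, replicate numbers at the points and bars for mean ± SD. Thalamus is highest in GFP control replicate 2 (11.39), interferon in Setd7 control replicate 4 (10.10) and meninges in Setd7 defeat replicate 1 (10.32).

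The next comparison asked what adult defeat does to mice with the GFP virus (GFP defeat, n = 4, against GFP control, n = 3). Dopamine neuron genes were higher after defeat in 26 of 28 (0.75, adjusted p = 2.73e-07, 0.644 with an estimated correlation), with Ntsr1 at 0.99 ± 0.33, Foxa1 at 0.91 ± 0.33 and Gucy2c at 1.27 ± 0.53. Without the 3 libraries with low Th, left out for that reason, the dopamine median was 0.18. Thalamus markers were lower in 10 of 11 (−0.48, adjusted p = 0.0273, 0.597 with an estimated correlation) and tectum markers in 6 of 6 (−0.87, adjusted p = 0.0273, 0.204 with an estimated correlation). GFP defeat replicate 4 was high in both thalamus (10.41) and dopamine genes (11.52), and GFP defeat replicate 1 was low in dopamine genes (9.99) with thalamus at 8.82.

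Oligodendrocyte genes were higher after defeat with GFP in 19 of 20 (0.22, adjusted p = 1.28e-06, 0.540 with an estimated correlation) and their precursor genes in 11 of 14 (0.17, adjusted p = 0.00177, 0.540 with an estimated correlation). Trf, the transferrin made by oligodendrocytes, was higher by 0.37 ± 0.09 and the lineage factor Olig1 by 0.30 ± 0.07, and each is the 1 member of its list that passes when adjusted over the list alone. C1ql1 (0.44 ± 0.14) and Olig2 (0.29 ± 0.10) followed. Without the 3 libraries with low Th the medians were 0.10 (adjusted p = 0.0562) and 0.00 (0.442), and without GFP control replicate 3 that of the precursors was 0.09 (0.0979). Ribosomal protein genes were higher in 40 of 43 (0.19, adjusted p = 3.85e-10, 0.195 with an estimated correlation, fry adjusted p = 0.0463; Rpl14 0.24 ± 0.07). Heat shock genes were higher in 23 of 24 (0.15, adjusted p = 1.28e-06, 0.471 with an estimated correlation), and Dnajb1 (0.32 ± 0.08) and Hsp90ab1 (0.24 ± 0.06) pass when adjusted over the list alone. The inducible chaperones Hspa1b (0.87 ± 0.28) and Hspa1a (0.66 ± 0.22) followed, which share reads and are uncertain singly. Clock genes were lower in 14 of 20 (−0.17, adjusted p = 0.00211, 0.540 with an estimated correlation; Bhlhe40 −0.31 ± 0.09, Clock −0.19 ± 0.07), with a median of −0.12 (0.0914) without GFP control replicate 3 and 0.06 (0.442) without the 3 libraries with low Th. Oxidative phosphorylation genes were higher in 29 of 36 (0.07, adjusted p = 0.00265, 0.848 with an estimated correlation; Ndufa2 0.47 ± 0.16, Atp5o 0.26 ± 0.11), at −0.02 (0.700) without GFP control replicate 1 and 0.05 (0.148) without GFP defeat replicate 2.

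By single genes, limma called 0 in the effect of defeat with GFP (1642 at unadjusted p under 0.05, 865 higher and 777 lower), edgeR 0 and DESeq2 85, 28 higher and 57 lower. The lower genes named by rule were Mir124a-1hg (2469 ± 270 to 1089 ± 248, −1.15 ± 0.18) and the cold-inducible RNA-binding protein Rbm3 (611 ± 81.3 to 369 ± 37.1, −0.67 ± 0.11). Next came Ttc14 (3559 ± 84.4 to 2506 ± 272), nebulin Neb (188 ± 96.5 to 49.6 ± 6.83, −1.68 ± 0.31) and the splicing factor kinase Clk1 (2324 ± 256 to 1426 ± 196, −0.71 ± 0.14), all with adjusted p = 0.339 by limma. Higher were the potassium channel Kcna3 (1195 ± 24.0 to 1719 ± 246, 0.52 ± 0.10) and the actin-severing gelsolin Gsn (2113 ± 193 to 2953 ± 234, 0.47 ± 0.09). They were followed by Tspyl3 (0.38 ± 0.07), Plpp2 (0.72 ± 0.14) and the zinc transporter Slc39a11 (509 ± 42.2 to 717 ± 45.6), also at 0.339. DESeq2 called Mir124a-1hg (adjusted p = 1.0e-05), Rbm3 (0.000413), Neb (0.000413), Ttc14 (0.000499) and Clk1 (0.00243). Named after their values were seen, and not tested as a group, are 5 more of its 57 lower genes: Rnpc3 (−0.74, adjusted p = 0.00358), Tia1 (−0.52, 0.00576), Pnisr (−0.52, 0.0229), Prpf39 (−0.43, 0.0345) and Clk4 (−0.42, 0.0345). Neb stood at −1.06 without the 3 libraries with low Th.

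Setd7 without defeat and defeat with GFP share their 3 control libraries. Across 17755 genes, which are not independent replicates, the 2 effects correlated with Pearson r = 0.686 (Spearman 0.679). With residuals permuted over samples, so that shared libraries alone relate the effects, the simulated r had a median of 0.610 and a central 95% range from −0.0557 to 0.825, with 26 of 100 at or above the observed value. The covariance was 0.0943 against a simulated median of 0.0854. At unadjusted p under 0.05, 376 genes were higher in both (37.3 if independent) and 309 lower in both (28.8 if independent), and part of this excess may come from the shared control libraries. DESeq2 called 12 genes in both, all 12 with the same sign: Cacng5, Cttnbp2, Dkk3, Hdac11, Hsp90ab1, Kifc2, Magee1, Mir124a-1hg, Peak1, Plpp2, Tspyl3 and Ttc14. The shared controls raise this overlap by themselves, by an amount not simulated here. The GFP control group cannot be split into parts of at least 2 libraries each.

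The third comparison asked what Setd7 does after defeat (Setd7 defeat, n = 2, against GFP defeat, n = 4). Genes of meningeal fibroblasts were higher with Setd7 in 15 of 16 (1.03, adjusted p = 5.12e-13, 0.701 with an estimated correlation), and 8 pass when adjusted over the list alone, 0 over all genes. These are the matrix genes Dcn (0.94 ± 0.26), Ogn (1.89 ± 0.54), Fn1 (0.87 ± 0.25) and Col1a1, the retinoic acid enzyme Aldh1a2 (1.77 ± 0.55), and the transporters Slc6a20a, Slc22a6 and Slc13a4. Endothelial and mural genes were higher in 20 of 21 (0.20, adjusted p = 4.71e-09, 0.317 with an estimated correlation), such as Rgs5 (0.46 ± 0.13), Pecam1 (0.39 ± 0.12) and Vtn (0.71 ± 0.25). Setd7 defeat replicate 1 had a meningeal mean of 10.32 against 7.88 in replicate 2, and without it the medians were 0.08 (adjusted p = 0.716) for meninges and 0.13 (0.174) for vessels.

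Interferon genes were higher with Setd7 after defeat in 25 of 26 (0.40, adjusted p = 0.00214, 0.815 with an estimated correlation; the MHC class II genes H2-Aa 3.29 ± 1.63 and Cd74 2.57 ± 1.41). Microglia genes were higher in 20 of 20 (0.24, adjusted p = 0.00214, 0.815 with an estimated correlation; Lyz2 1.25 ± 0.54, Aif1 1.31 ± 0.58). Reactive glia genes were higher in 15 of 19 (0.49, adjusted p = 0.00257, 0.814 with an estimated correlation; Gpnmb 1.60 ± 0.58, Apoe 0.31 ± 0.12). Leaving out Setd7 defeat replicate 1 gave these 3 lists medians of −0.18 (adjusted p = 0.5996), 0.11 (0.5996) and 0.21 (0.456), and without GFP defeat replicate 4 that of interferon genes was 0.21 (0.0917). Heat shock genes were higher in 18 of 24 (0.07, adjusted p = 0.0194, 0.814 with an estimated correlation; Hspe1 0.38 ± 0.13). Clock genes were lower in 16 of 20 (−0.11, adjusted p = 0.0165, 0.814 with an estimated correlation; Cry2 −0.17 ± 0.08, Tef −0.20 ± 0.10). Leaving out Setd7 defeat replicate 2 gave 0.04 (0.381) and −0.05 (0.344), and heat shock was 0.08 (0.118) or 0.06 (0.0623) without GFP defeat replicates 2 or 3. Dopamine neuron genes had a median of 0.18 (26 of 28 higher, adjusted p = 0.0734) and ribosomal genes 0.02 (adjusted p = 0.373).

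Among single genes limma called 0 for Setd7 after defeat (862 at unadjusted p under 0.05), edgeR 0 and DESeq2 6. The genes named by rule that were higher with Setd7 were Tinagl1 (264 ± 30.9 to 486 ± 177, 0.83 ± 0.17), thrombomodulin Thbd (482 ± 70.0 to 1424 ± 1097, 1.32 ± 0.28) and the endothelial receptor Adgrl4 (1123 ± 59.3 to 1461 ± 142). Next came Sft2d3 (245 ± 19.95 to 383 ± 2.87) and Lsm3 (0.50 ± 0.12), all with adjusted p = 0.990 by limma. Lower were Lemd1 (−0.98 ± 0.24), Ccser1 (−0.43 ± 0.11), the Elongator subunit Elp2 (1690 ± 31.4 to 1403 ± 15.5), the serotonin receptor Htr7 (1118 ± 43.0 to 777 ± 77.2, −0.53 ± 0.14) and Cdadc1 (−0.28 ± 0.08). Without Setd7 defeat replicate 1 Tinagl1 was 0.51 and Thbd 0.52, and without replicate 2 (each n = 1) Thbd was 2.12. Cdadc1 was −0.18 without the 2 libraries high in interferon genes (Setd7 control replicate 4 and Setd7 defeat replicate 1). DESeq2 called Setd7, the epithelial cadherin Cdh1 (4.4045, adjusted p = 0.000263; 304 ± 391 in Setd7 defeat), Thbd (1.47, 0.000263), Prg4 (2.74, 0.00333), Tinagl1 (0.86, 0.0108) and Slc47a1 (2.93, 0.02).

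Defeat in mice with the Setd7 virus (Setd7 defeat, n = 2, against Setd7 control, n = 4) was compared to ask whether the response changes with the methyltransferase raised. Meningeal genes were higher in 16 of 16 (1.06, adjusted p = 1.06e-17, 0.256 with an estimated correlation), and 6 pass when adjusted over the list alone: Aldh1a2 (2.01 ± 0.55), Slc22a6 (2.38 ± 0.72), Fn1 (0.79 ± 0.25), Ogn (1.71 ± 0.54), Col1a1 (1.06) and Slc13a4 (2.33). Endothelial genes were higher in 19 of 21 (0.22, adjusted p = 4.23e-11, 0.186 with an estimated correlation; Flt1 0.22 ± 0.07, Pecam1 0.36 ± 0.12). Without Setd7 defeat replicate 1 the medians were 0.01 (adjusted p = 0.806) and 0.06 (0.161). Genes of GABA neurons were higher in 15 of 18 (0.15, adjusted p = 0.0107, 0.963 with an estimated correlation), led by the fate factors Gata3 (0.79 ± 0.33) and Gata2 (0.55 ± 0.24), with 0.16 (0.292) without replicate 1 and 0.27 (0.0666) without replicate 2. Oligodendrocyte genes were higher in 19 of 20 (0.10, adjusted p = 0.0044, 0.963 with an estimated correlation; Gjb1 0.28 ± 0.16). Blood genes were higher in 5 of 6 (0.72, adjusted p = 0.0107, 0.1997 with an estimated correlation; Pf4 1.77 ± 0.75, Slc4a1 1.13 ± 0.67), and heat shock genes in 17 of 24 (0.05, adjusted p = 0.0228, 0.963 with an estimated correlation; Xbp1 0.20 ± 0.11). Leaving out Setd7 defeat replicate 2 gave these 3 lists 0.03 (0.903), 0.04 (0.390) and 0.05 (0.719). Oligodendrocyte and heat shock genes had 0.04 (0.232) and 0.03 (0.232) without Setd7 control replicate 3, and heat shock genes 0.05 (0.188) without replicate 4. Dopamine neuron genes had a median of −0.05 (12 of 28 higher, adjusted p = 0.970), ribosomal genes 0.03 (0.626) and clock genes −0.02 (0.626).

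For defeat with Setd7, limma called 0 single genes (459 at unadjusted p under 0.05, below the 887.75 expected by chance), edgeR 0 and DESeq2 7. Sox1ot was higher after defeat (361 ± 13.5 to 631 ± 24.5, 0.80 ± 0.15), as were Thbd (1.19 ± 0.28), Bace2 (0.86 ± 0.21), Adgrl4 (0.33 ± 0.08) and Slc26a7 (1.97 ± 0.50), each with adjusted p = 0.9999 by limma. Sox1ot overlaps Sox1 and strand was not used here, so its reads are uncertain, with Sox1 itself at 0.10 ± 0.09. Lower were Elp2 (−0.27 ± 0.07), AU040972 (−1.45 ± 0.43), Atp13a4 (−0.44 ± 0.13), Pfdn6 (−0.45 ± 0.13) and Ldoc1 (−0.83 ± 0.25). Without Setd7 defeat replicate 1 Thbd was 0.39, Bace2 0.53, Slc26a7 1.22, AU040972 −0.68 and Ldoc1 −0.48. Without replicate 2 (each n = 1) Thbd was 1.99 and AU040972 −2.22. DESeq2 called Thbd (1.34, adjusted p = 0.0111), Sox1ot (0.81, 0.0136), Cdh1 (3.66, 0.0164), Col6a2 (1.74), Slc47a1 (2.87), Aldh1a2 (2.23) and Prg4 (2.38).

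Whether defeat acts differently with Setd7 was read from the interaction (all 4 groups, n = 3, 4, 4 and 2). Dopamine neuron genes responded less to defeat with Setd7 than with GFP in 25 of 28 members (−0.66, adjusted p = 8.28e-05, 0.927 with an estimated correlation; Foxa1 −1.15 ± 0.50, Ntsr1 −1.11 ± 0.49). So did ribosomal genes in 31 of 43 (−0.23, adjusted p = 3.08e-05, 0.497 with an estimated correlation; Rpl14 −0.34 ± 0.10), and oxidative phosphorylation genes in 27 of 36 (−0.09, adjusted p = 0.0307, 0.927 with an estimated correlation; Atp5g3 −0.42 ± 0.17). Meningeal genes responded more in 16 of 16 (1.36, adjusted p = 2.82e-11, 0.497 with an estimated correlation; Ogn 2.35 ± 0.73, Aldh1a2 2.16 ± 0.73) and endothelial genes in 18 of 21 (0.17, adjusted p = 3.08e-05, 0.497 with an estimated correlation; Rgs5 0.53 ± 0.18). The dopamine value was −0.52 (adjusted p = 0.0760) without GFP control replicate 3, −0.43 (0.0672) without GFP defeat replicate 4 and −0.11 (0.537) without the 3 libraries with low Th. Endothelial genes were at 0.20 (0.0635) in that setting. Leaving out Setd7 defeat replicate 1 put meninges at 0.27 (0.349) and vessels at 0.13 (0.338). Ribosomal genes were at −0.07 (0.111) without replicate 2, and without GFP control replicate 1 oxidative phosphorylation was at 0.00 (0.911). The last call also ends without GFP control replicate 2 (−0.10, 0.0777), GFP defeat replicate 2 (−0.06, 0.237) or 3 (−0.09, 0.101), Setd7 control replicate 1 (−0.06, 0.205) or Setd7 defeat replicate 1 (−0.12, 0.338). Thalamus markers differed by 0.54 (adjusted p = 0.0224, 0.682 with an estimated correlation) and tectum markers by 1.67 (adjusted p = 0.0224, 0.144 with an estimated correlation). Heat shock genes (−0.12, 0.0595), clock genes (0.17, 0.0734), interferon genes (−0.04, 0.777) and oligodendrocyte genes (−0.04, 0.137) were not called.

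In the interaction limma called 0 genes (880 at unadjusted p under 0.05), edgeR 0 and DESeq2 1, Cdh1 (5.51, adjusted p = 0.00486). Genes with a more positive response to defeat under Setd7 were Cacng5 (1.43 ± 0.34), Fam163a (0.85 ± 0.20), Rbms1 (0.71 ± 0.17), Sft2d3 (0.79 ± 0.19) and Pde3a (1.06 ± 0.25). A more negative response was seen in Mfsd13a (−0.60 ± 0.12), Tspyl3 (−0.50 ± 0.11), the histone gene H2ac6 (−1.71 ± 0.40, which shares reads with near-identical copies and is uncertain), Ndufc2 (−0.55 ± 0.13) and Smim10l2a (−0.50 ± 0.12), all with adjusted p = 0.942 by limma. Cacng5 was 0.89 without Setd7 control replicate 4 and Setd7 defeat replicate 1, the 2 libraries high in interferon genes.

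Setd7 and defeat together were compared with neither (Setd7 defeat, n = 2, against GFP control, n = 3). Heat shock genes were higher in 23 of 24 (0.25, adjusted p = 7.25e-10, 0.177 with an estimated correlation), and 6 pass when adjusted over the list alone, Hspa1a (1.06 ± 0.26), Hspa1b (1.24 ± 0.34), Pdia4 (0.43 ± 0.11), Hsp90ab1 (0.26 ± 0.07), Dnajb1 (0.31) and Hspb1 (0.78). Dopamine neuron genes were higher in 26 of 28 (0.93, adjusted p = 8.72e-10, 0.380 with an estimated correlation; Sncg 0.97 ± 0.27). Ribosomal genes were higher in 42 of 43 (0.23, adjusted p = 1.66e-10, 0.177 with an estimated correlation; Rps6 0.47 ± 0.11, Rpl3 0.38 ± 0.11). Clock genes were lower in 18 of 20 (−0.24, adjusted p = 4.42e-07, 0.180 with an estimated correlation; Bhlhe40 −0.36 ± 0.10, Nr1d1 −0.41 ± 0.13). Oligodendrocyte genes (0.27, adjusted p = 1.09e-06), their precursors (0.17, 0.00239), oxidative phosphorylation (0.11, 4.19e-05), blood (0.56, 0.0140) and, lower, receptors (−0.14, 0.0140) and ion channels (−0.16, 0.0154) were also called, with adjusted p of 0.380, 0.380, 0.504, 0.180, 0.503 and 0.380 with an estimated correlation. Meningeal (0.89, 2.82e-06), endothelial (0.27, 4.11e-06), interferon (0.73, 0.00164), microglia (0.36, 0.00743) and reactive glia genes (0.35, 0.0314) were higher, with adjusted p of 0.438, 0.193, 0.575, 0.575 and 0.504 with an estimated correlation. Without Setd7 defeat replicate 1 the meningeal median was −0.13 (0.678), the interferon median −0.09 (0.937) and the endothelial median 0.11 (0.188), with microglia at 0.10 (0.678), reactive glia at 0.17 (0.695), receptors at 0.01 (0.936) and ion channels at −0.04 (0.651). Oligodendrocyte genes had 0.13 (0.108), precursors 0.13 (0.628) and blood 0.31 (0.222) without Setd7 defeat replicate 2, and oxidative phosphorylation 0.01 (0.505) without GFP control replicate 1. Leaving out GFP control replicate 2 gave microglia 0.25 (0.0673), reactive glia 0.30 (0.138), receptors −0.07 (0.388), ion channels −0.15 (0.0626) and blood 0.55 (0.0509). Without GFP control replicate 3 ion channels had −0.07 (0.0527), blood 0.40 (0.0538) and precursors 0.12 (0.0547). Thalamus markers were at −0.93 (0.00229, 0.908 with an estimated correlation), and without the 3 libraries with low Th the dopamine median was 0.07 (0.639). In that setting the other lists that lose their call were clock (−0.06, 0.454), microglia (0.00, 0.955), interferon (0.21, 0.567), reactive glia (0.05, 0.569), blood (0.18, 0.601), oligodendrocyte (0.12, 0.0706), precursor (0.05, 0.569), receptor (−0.07, 0.307) and ion channel genes (0.00, 0.894).

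Single genes called for Setd7 and defeat together were 0 by limma (1473 at unadjusted p under 0.05), 0 by edgeR and 26 by DESeq2. Among the genes named by rule, higher were Adgra3 (0.49 ± 0.09), the Wnt receptor Fzd2 (0.84 ± 0.16), both with adjusted p = 0.441 by limma, and Lamc1 (0.42 ± 0.09, adjusted p = 0.515). Tpt1 (0.45 ± 0.09) and Rpl41 (0.54 ± 0.11) were higher too, with reads shared among copies and so uncertain. Ttc14 (−0.57 ± 0.10), Mbd6 (−0.66 ± 0.14) and Rbm3 (−0.61 ± 0.13) were lower, as were Pisd-ps3 (−0.73 ± 0.13) and Pisd-ps1 (−0.68 ± 0.13), which share reads with each other and are uncertain. Fzd2 was 0.55 without Setd7 defeat replicate 1. Setd7 stood at 2.87 ± 0.48 (adjusted p = 0.441 by limma, 0.413 by edgeR and 0.000712 by DESeq2), and at 2.92 (adjusted p = 0.000359 by limma) without Setd7 control replicate 4.

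Averaged over defeat, Setd7 was the 1 gene called by limma (1265 at unadjusted p under 0.05), the 1 called by edgeR, and 1 of 7 called by DESeq2 with Adgra3 (0.30, adjusted p = 0.00505), Prg4, Bsg, Rpl41, Alas1 and Tpt1. By limma Adgra3 was higher by 0.30 ± 0.05, Tpt1 by 0.28 ± 0.06, Rpl41 by 0.33 ± 0.07, the heme enzyme Alas1 by 0.23 ± 0.05 and Susd2 by 0.34 ± 0.07. Lower were Wnt9b (−4.00 ± 0.91; 124 ± 142, 32.5 ± 44.4, 8.30 ± 13.9 and 0 counts in GFP control, GFP defeat, Setd7 control and Setd7 defeat, and −2.54 with 5 instead of 1 added before the logarithm), Ccser1 (−0.31 ± 0.07), Epha1 (−0.91 ± 0.21), Wdr90 (−0.53 ± 0.13) and Hnrnpa3 (−0.20 ± 0.05), all with adjusted p = 0.686. Camera called dopamine neuron genes (0.56, 26 of 28 higher, adjusted p = 5.56e-10; Sncg 0.61 ± 0.17), ribosomal genes (0.10, 36 of 43, 2.87e-08) and heat shock genes (0.13, 21 of 24, 5.04e-08), at 0.446, 0.206 and 0.210 with an estimated correlation. Clock genes were lower (−0.17, 19 of 20, 2.87e-08, 0.206 with an estimated correlation; Nr1d1 −0.26 ± 0.08, Per3 −0.20 ± 0.07), at −0.05 (0.0481) without the 3 libraries with low Th. Ribosomal members passing when adjusted over the list alone were 7, among them Rps6 (0.28 ± 0.07) and Rpl4 (0.17 ± 0.05), against 0 over all genes. Interferon (0.58, 25 of 26, 1.35e-06), microglia (0.31, 4.7e-05), meningeal (0.48, 7.04e-05), endothelial (0.15, 4.7e-05) and reactive glia genes (0.27, 0.00186) were called higher, with adjusted p of 0.446, 0.446, 0.446, 0.372 and 0.446 with an estimated correlation. Leaving out Setd7 defeat replicate 1 gave 0.19 (0.157) for interferon, 0.17 (0.0622) for microglia and 0.02 (0.620) for meninges, with endothelial genes at 0.06 (0.157), reactive glia at 0.21 (0.157), receptors at −0.01 (0.620) and ion channels at −0.01 (0.325). Oxidative phosphorylation (0.07, 4.26e-06), oligodendrocyte (0.07, 0.00561), receptor (−0.08, 0.00421) and ion channel genes (−0.07, 0.00965) were called with adjusted p of 0.446, 0.563, 0.446 and 0.408 with an estimated correlation. Oxidative phosphorylation was 0.02 (0.0860) without GFP control replicate 1, receptors −0.04 (0.125) without GFP control replicate 2, and oligodendrocyte genes 0.04 without GFP control replicate 2 (0.125), GFP defeat replicate 1 (0.128) or Setd7 defeat replicate 2 (0.603). With the 3 libraries with low Th left out, microglia were at 0.16 (0.216), reactive glia at 0.28 (0.0648), oligodendrocyte genes at 0.00 (0.834), receptors at −0.04 (0.161) and ion channels at −0.01 (0.395). Thalamus markers were at −0.58 (0.000131, 0.720 with an estimated correlation), and the synaptic organizer Cbln2 (−0.74 ± 0.20) was the 1 excitatory marker to pass when adjusted over the list alone.

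The effect of defeat averaged over virus gave 0 genes by limma (919 at unadjusted p under 0.05), 0 by edgeR and 8 by DESeq2. Sox1ot (0.68 ± 0.10, adjusted p = 0.331 by limma, 1.64e-05 by DESeq2), Fzd2 (0.51 ± 0.10), Gsn (0.34 ± 0.07), Niban2 (0.29 ± 0.07) and Carhsp1 (0.22 ± 0.06) were higher after defeat. Rbm3 (−0.42 ± 0.08), Ttc14 (−0.32 ± 0.06), Pisd-ps3 (−0.40 ± 0.08), Pisd-ps1 (−0.37 ± 0.08) and Mbd6 (−0.39 ± 0.09) were lower. All but Sox1ot had adjusted p = 0.922 by limma. Oligodendrocyte (0.17, adjusted p = 2.69e-08), precursor (0.13, 0.000125), ribosomal (0.10, 41 of 43 higher, 2.69e-08), heat shock (0.10, 23 of 24, 9.63e-08) and dopamine neuron genes (0.35, 4.66e-05) were called higher, with adjusted p of 0.413, 0.358, 0.177, 0.220 and 0.718 with an estimated correlation. Trf (0.27 ± 0.07) passes when adjusted over the list alone. Meningeal (0.36, 4.19e-05), endothelial (0.13, 0.000125), blood (0.35, 0.00293), oxidative phosphorylation (0.03, 0.0370) and clock genes (−0.07, 0.00305) were called too, with adjusted p of 0.655, 0.358, 0.177, 0.838 and 0.4932 with an estimated correlation. Meninges stood at −0.10 (0.543) and vessels at 0.04 (0.328) without Setd7 defeat replicate 1. Leaving out Setd7 defeat replicate 2 gave blood 0.27 (0.120), clock −0.11 (0.196) and precursors 0.11 (0.230). The oxidative phosphorylation call ends without any of 8 libraries, and its median was −0.02 (0.648) without GFP control replicate 1. Dopamine neuron genes were at 0.03 (0.497), clock genes at 0.03 (0.593), blood at 0.12 (0.395) and precursors at 0.07 (0.124) without the 3 libraries with low Th.

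**Figure D3:**
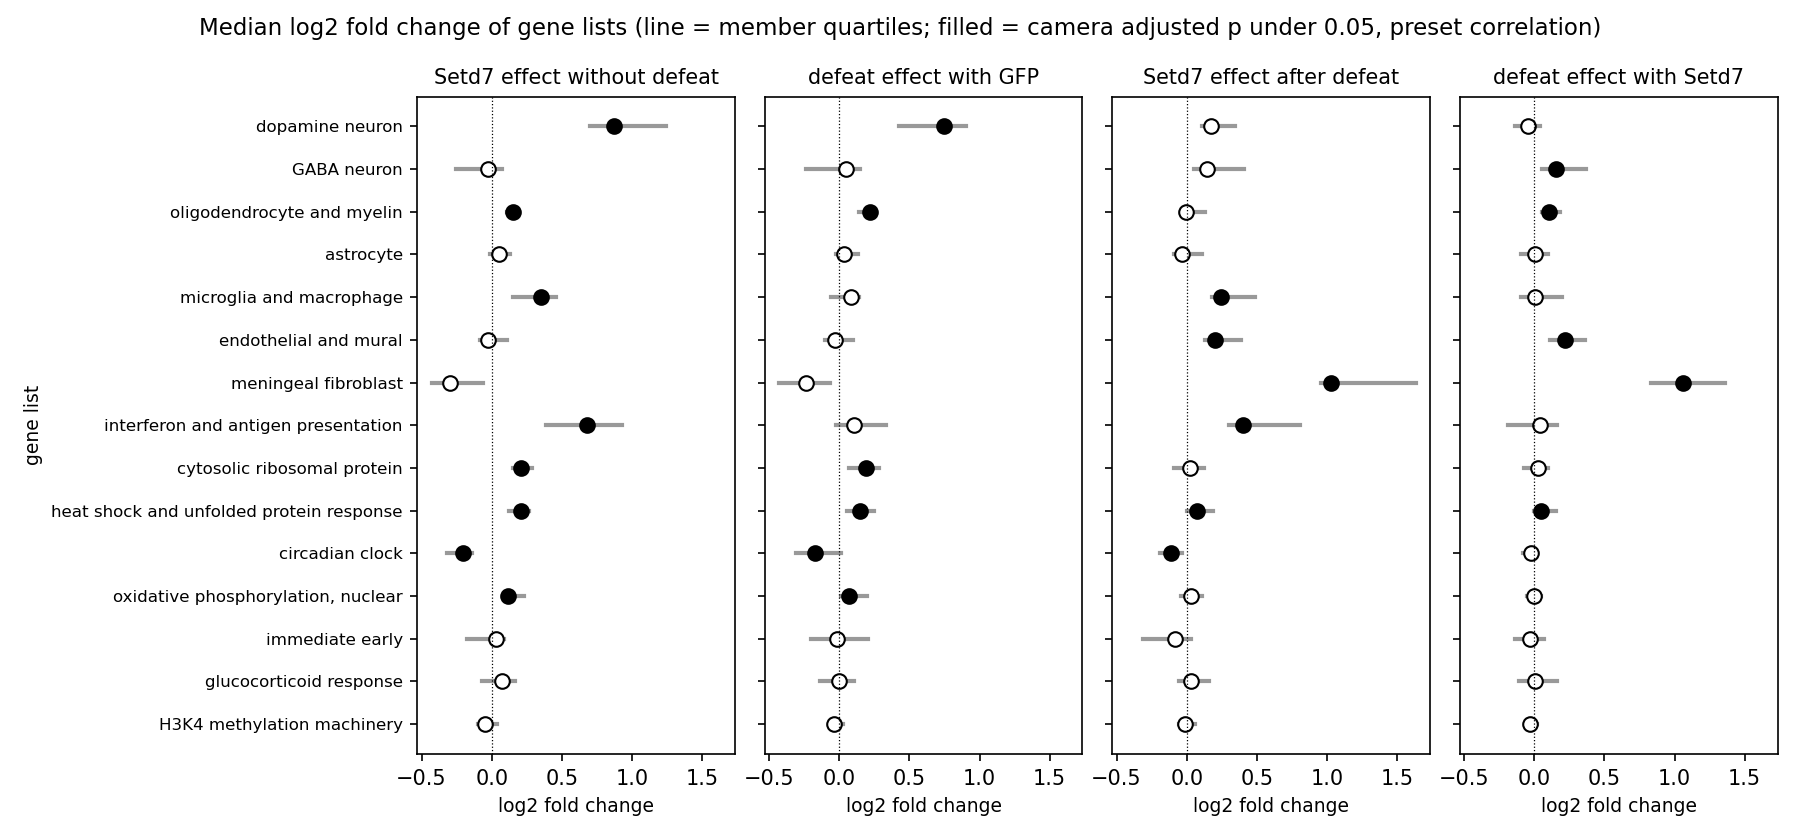
Median log2 fold change of 15 gene lists (horizontal axis) in the 4 single comparisons, where lines join the quartiles of members and filled points passed camera with the preset correlation. Dopamine neuron genes stand at 0.87, 0.75, 0.18 and −0.05.

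The effect of Setd7 without and after defeat, in groups with 0 shared libraries, correlated across genes with r = 0.128 (Spearman 0.103), against a simulated median of −0.0378 and 95% range from −0.541 to 0.498, with 24 of 100 at or above it. The covariance was 0.0194 against a simulated median of −0.00585. At unadjusted p under 0.05, 39 genes were higher in both (19.8 if independent) and 27 lower in both (14.9 if independent). Without the 3 libraries with low Th r was −0.0170, and it was 0.0271 without Setd7 control replicate 4, 0.0569 without GFP control replicate 2 and 0.0760 without Setd7 defeat replicate 1. The effects of defeat with GFP and with Setd7 correlated with r = 0.0166 (Spearman 0.0112; simulated median 0.0120, 95% range from −0.553 to 0.499, 49 of 100 at or above). Counted at unadjusted p under 0.05, 4 genes were higher in both (12.6 if independent) and 14 lower in both (8.80 if independent).

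Several lists were called in none of the 8 comparisons between groups. For Setd7 without defeat and defeat with GFP, immediate early genes had medians of 0.03 (adjusted p = 0.523; mean −0.13 and the test downward, with Nptx2 −1.11 ± 0.44) and −0.01 (0.693; Sik1 0.23 ± 0.09, Nr4a3 0.44 ± 0.18). Glucocorticoid-responsive genes had 0.07 (0.560; Cdkn1a 0.58 ± 0.18) and −0.00 (0.938; the mean was 0.03, and Mertk −0.33 ± 0.12). Machinery of histone H3 lysine 4 methylation had −0.05 (0.285; Kmt2b −0.23 ± 0.08) and −0.03 (0.305; Cxxc1 −0.22 ± 0.08), and other chromatin regulators −0.04 (0.149; Dot1l −0.27 ± 0.11) and −0.04 (0.189; Dot1l −0.37 ± 0.11). Synaptic genes had 0.03 (0.787; Unc13b −0.43 ± 0.12) and 0.01 (0.734; Nrxn2 0.24 ± 0.06), and neuropeptides 0.03 (0.784) and 0.10 (0.189; Vgf 0.32 ± 0.10). Astrocyte genes had 0.05 (0.0574) and 0.03 (0.184), perineuronal net genes −0.05 (0.907) and −0.01 (0.877), and p53 targets 0.08 (0.0720) and 0.05 (0.532). Choroid plexus genes had −0.04 (0.979) and 0.01 (0.734), and genes of neighbouring nuclei 0.16 (0.907) and −0.03 (0.919). For defeat with Setd7 the neighbouring nuclei had a median of −0.00 and a mean of −0.17 (adjusted p = 0.733).

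Females (n = 6) were compared with males (n = 7) as a check of the labels, with 11 genes called by limma, 10 by edgeR and 17 by DESeq2. Xist rose in females by 10.46 ± 0.33 with its antisense Tsix (3.27, uncertain because strand was not used). Genes escaping X inactivation rose: Eif2s3x (0.61 ± 0.05, adjusted p = 2.59e-05), Kdm6a (0.60 ± 0.06), Ddx3x (0.45 ± 0.05) and Kdm5c (0.40 ± 0.04). The Y genes Ddx3y (−11.52), Uty (−10.20), Kdm5d (−9.69), Eif2s3y (−9.05) and Uba1y (−3.81) fell. Xist ran from 18793 to 39253 in females and 6.46 to 36.4 in males, and Ddx3y from 2732 to 3431 in males with 0 in every female. Every library matches its stated sex, and the fitted value of Ddx3y depends on the count of 1 added before the logarithm. Prolactin Prl was higher in females (5.44 ± 0.93, adjusted p = 0.0979 by limma, 0.0388 by edgeR, 2.94e-05 by DESeq2). Females read 2.18 to 460, with Gh high where Prl was highest (below), so pituitary tissue may give this. Trpv4 (1.02 ± 0.20), Fam83d (0.75 ± 0.15), Nlrp5-ps (0.66) and D1Pas1 (0.45) followed upward, the last a copy of Ddx3x and, like Nlrp5-ps, uncertain. Orai2 (−0.27 ± 0.06), Itgae (−1.39 ± 0.34), Rbm3 (−0.33 ± 0.08), Zfp703 (−0.28) and Cpne6 (−0.21) led downward. Setd7 was at 0.45 ± 0.29 (adjusted p = 0.999), and at 0.14 without Setd7 control replicate 4 or 0.29 without replicate 1.

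Between the sexes camera called meningeal genes (0.51, 16 of 16 higher in females, adjusted p = 3.10e-07, 0.496 with an estimated correlation) and ribosomal genes (−0.08, 39 of 43 lower, 1.11e-06, 0.470 with an estimated correlation; Rpl6 −0.22 ± 0.06). It also called interferon genes (−0.31, 26 of 26 lower, 0.00259, 0.770 with an estimated correlation), oligodendrocyte (0.10, 0.000630), clock (−0.10, 0.00112) and heat shock genes (0.07, 0.0138), the latter 3 at 0.559, 0.470 and 0.520 with an estimated correlation. Meningeal genes were at 0.18 without either Setd7 defeat library (0.107 without replicate 1, 0.105 without replicate 2), and interferon genes at 0.13 (0.0639) without Setd7 control replicate 4 and −0.22 without replicates 1 (0.108) or 2 (0.0542). Clock and oligodendrocyte genes were at −0.03 (0.348) and 0.04 (0.170) without GFP control replicate 1, and heat shock genes at 0.07 (0.188), 0.08 (0.0941) and 0.08 (0.0844) without Setd7 control replicates 1, 3 and 4. Precursor genes (0.07, 0.0353), other chromatin (−0.04, 0.0353), synaptic (−0.05, 0.0353) and ion channel genes (−0.05, 0.0404) were called with the preset correlation, with adjusted p of 0.559, 0.470, 0.502 and 0.496 with an estimated correlation. Each of these 4 loses its call without at least 5 of the libraries, left out in turn. Thalamus markers were lower in 11 of 11 (−0.59, 8.44e-05, 0.681 with an estimated correlation). The 3 libraries high in thalamus genes, GFP control replicates 2 and 3 and GFP defeat replicate 4 (11.39, 9.52 and 10.41), are all male, and the other 4 males lay at 8.47 to 8.94 against 8.07 to 8.97 in females. Of the regulators of lysine 4 methylation 2 pass over all genes (Kdm6a and Kdm5c) and 4 when adjusted over the list alone, adding Kmt2d (−0.19 ± 0.05) and Setd1b (−0.18 ± 0.05).

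Whether Setd7 acts differently by sex (6 female, 7 male libraries) gave 0 genes by limma (531 at unadjusted p under 0.05), edgeR and DESeq2. Dnajc28 (0.64 ± 0.16), the Wnt receptor Fzd1 (0.69 ± 0.18), Banf1 (0.45), Lhx9 (2.43 ± 0.66) and Hspa1a (0.84, uncertain as above) had more positive effects of Setd7 in females. C1ql3 (−0.97 ± 0.25), Creb5 (−0.53), Pou2f2 (−0.79), ghrelin Ghrl (−0.98) and the DNA sensor Cgas (−1.54 ± 0.44) had more negative ones, all with adjusted p = 0.999 by limma. Glucocorticoid-responsive genes had the smallest list p (0.28, adjusted p = 9.75e-08, 0.3997 with an estimated correlation), with Per1 at 0.41 ± 0.12, Plin4 at 1.01 ± 0.31 and Klf9 at 0.28 ± 0.10. Setd7 itself differed by 0.94 ± 0.54 (adjusted p = 0.999), by 0.32 without Setd7 control replicate 4 and by 1.62 without either Setd7 defeat library. Without the 2 high-interferon libraries Creb5 was −0.29 and Lhx9 1.61. Lhx9 was high (421 to 1444) only in male GFP libraries, which may give its value.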

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

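Tests chosen only after the result was seen are those of scaling and of regional markers for dopamine neuron genes, of Setd7 control replicate 4 and of Setd7 level for interferon genes, and of dopamine neuron content for ribosomal and clock genes.

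A library lay far from the others of its group in 19 of 220 values tested (groups of 4 only), where chance gives about 1 in 20 groups, or 11. Of these 1 is a library size, 13 are named genes and 5 are list means. In GFP defeat they are Wdr90 in replicate 1 (280, others 206 to 218), Ldoc1 in replicate 2 (172, others 105 to 114), Rbms1 in replicate 1 (637, others 717 to 732), Susd2 in replicate 2 (1257, others 968 to 1007), Prl in replicate 2 (460, others 0 to 14.9), Nlrp5-ps in replicate 3 (578, others 941 to 983), the microglia mean in replicate 1 (8.83, others 8.92 to 8.93) and the endothelial mean in replicate 4 (9.63, others 9.48 to 9.50). In Setd7 control they are the reads of replicate 2 (48.4 mega-reads, others 33.1 to 35.6), Dkk3 in replicate 4 (3926, others 3173 to 3256), Sft2d3 in replicate 2 (292, others 254 to 260), Cdadc1 in replicate 4 (1360.01, others 1292 to 1302), Bace2 in replicate 2 (129.8, others 115 to 116), Pisd-ps3 in replicate 3 (5198, others 4187 to 4300), Wnt9b in replicate 3 (29.1, others 0 to 2.97) and Prl in replicate 2 (57.9, others 0 to 2.18). List means in Setd7 control were the interferon mean in replicate 4 (10.10, others 6.95 to 7.14), the ion channel mean in replicate 1 (12.25, others 12.18 to 12.19) and the p53 mean in replicate 3 (8.99, others 9.06 to 9.07).

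The response of a list to defeat differed between viruses by the interaction test for dopamine neuron genes (−0.66), endothelial genes (0.17), meningeal genes (1.36), oxidative phosphorylation (−0.0905) and ribosomal genes (−0.23), with a smallest adjusted p of 0.497 with an estimated correlation. The effect of Setd7 differed between females and males for GABA neuron genes (0.17, adjusted p = 0.0496), endothelial genes (0.0864, 0.0274), meningeal genes (0.88, 9.13e-06), choroid plexus genes (0.57, 0.00628; Ttr 4.18 ± 1.53), glucocorticoid response (0.28, 9.75e-08), interferon genes (−0.54, 0.00628), oxidative phosphorylation (0.11, 0.000329), ribosomal genes (0.11, 0.0142), heat shock genes (0.0731, 0.00628) and clock genes (0.15, 0.000538), with a smallest adjusted p of 0.3997 with an estimated correlation. Without Setd7 control replicate 4 the interferon difference was 0.36 (adjusted p = 0.00197), and without either Setd7 defeat library the meningeal difference was 0.09 (0.756). Clock genes (0.06, 0.292) and oxidative phosphorylation (0.01, 0.613) lose the call without GFP control replicate 1, and choroid plexus genes (0.11, 0.352) without GFP defeat replicate 4. Choroid plexus, interferon, GABA neuron, endothelial, ribosomal and heat shock genes each lose it without at least 3 of the libraries, left out in turn.

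Dopamine neuron genes were higher in Setd7 control (n = 4) than in GFP control (n = 3), with a median of 0.87. Equal totals and upper quartile scaling gave at least 0.847, but they move all genes together by only −0.0259 and −0.0179, so these settings decide nothing. Of the 35 splits of these 7 libraries 6 gave a median as large (highest other 1.32), so chance is not excluded. Markers of the thalamus were at −0.967 in Setd7 control, opposite to the dopamine genes, which a scaling factor shared by all genes of a library cannot give, so tissue from a neighbouring region in the GFP control punches may account for the difference, and a share of dopamine neurons that Setd7 alters stays open beside it. GFP defeat replicate 1 is low in dopamine neuron genes (9.99) at a thalamus mean of 8.82, and GFP defeat replicate 4 is high in both (11.52 and 10.41), so thalamic tissue alone leaves these 2 libraries unexplained.

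Interferon genes were higher in Setd7 control than in GFP control, with a median of 0.68. Without Setd7 control replicate 4 the median was −0.104, so that library alone may carry the pattern, and 26 of 35 splits gave a median as large (highest other 1.47), so chance is not excluded. Over the 6 Setd7 libraries the list mean fell with Setd7 (Pearson r = −0.895, exact permutation p = 0.0486 two-sided). By Spearman it was −0.657 (p = 0.175). This was the 1 relation computed, and without Setd7 control replicates 4 and 1 r was −0.204. The relation rests on those samples and decides nothing about Setd7 level. An infection or immune reaction in single animals stays open and was not tested.

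Ribosomal protein genes were higher (0.21) and clock genes lower (−0.21) in Setd7 control than in GFP control. Of the 35 splits only the real one gave a ribosomal median as large (1 of 35, the smallest share possible, real value 0.207, highest other 0.183), which excludes chance for this list taken alone, but not after choosing it among 28 lists, and its adjusted p was 0.111 with an estimated correlation. After removing the trend with transcript length and GC content over the 43 of 43 members with a length the ribosomal median was 0.207, and with dopamine neuron content as a covariate 0.186, which argues against both as its source, while the clock median was −0.16 with the covariate. Clock means were 10.55, 10.93 and 10.88 in GFP control replicates 1, 2 and 3, against 10.47 to 10.66 in the other groups. Ribosomal means were 8.93, 9.07 and 9.11, against 9.09 to 9.335. The covariance of the Setd7 and defeat effects was 0.0943, within the simulated range of −0.0286 to 0.199. A trait of the shared GFP control libraries, for clock genes of replicates 2 and 3, may thus underlie the change seen in both comparisons. An effect of Setd7 on ribosomal genes stays open beside it.

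Other splits of the samples gave as many genes at unadjusted p under 0.05 as the real groups in 4 of 35 for Setd7 without defeat (1423, highest other 1616), 3 of 35 for defeat with GFP (1642, highest other 1894), 7 of 100 for Setd7 averaged over defeat (1265, highest other 2217), 37 of 100 for defeat averaged over virus (919, highest other 2500), 57 of 100 for sex (687, highest other 1893) and 72 of 100 for the Setd7 effect by sex (531, highest other 2274). As many called lists came in 16 of 35 (10, highest other 14), 25 of 35 (7, highest other 13), 10 of 100 (13, highest other 16), 46 of 100 (10, highest other 16), 39 of 100 (10, highest other 16) and 48 of 100 (10, highest other 18). Chance is excluded in none of these 12. For genes past the threshold chance is excluded for sex (11, 1 of 100 splits, highest other 1), for that count taken alone. For Setd7 averaged over defeat 3 of 100 splits gave as many (1, highest other 7). The 1 gene is Setd7 itself, which the virus carries, so this count tells nothing of other genes. A split with more genes than the real groups leaves chance open for it. The splits that gave 2500, 1893 and 2274 genes, against 919, 687 and 531, point to a structure of the samples other than the groups, which was not tested.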

How the results depend on the processing

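Leaving out the 3 libraries with low dopamine neuron genes and leaving out the 2 libraries with high interferon genes were chosen after the data had been seen, and the count of comparisons in which each list is called was defined after the list results had been seen. No paired analysis was possible because replicate numbers were given in accession order and mark no shared animal, litter or day. The 114 named gene values and 93 list calls were compared under each alternative, and named genes are compared by direction and threshold. Where leaving out libraries leaves a group with 1 sample (Setd7 defeat without either of its libraries or without the 2 with high interferon genes, GFP control without the 3 with low dopamine neuron genes), limma takes that sample to vary like the other groups. Using only the groups compared was not run for the averaged effects and the interaction, which need all groups. At depths of 26.5 to 50.8 mega-reads 8509 genes that reached 10 normalized counts in fewer than 2 samples were left untested. What more or less depth would change was not tested. Unless said otherwise, the cause of a difference was not tested.

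All 114 named gene values kept direction and side of the threshold with pseudocount 0.5 and 108 of 108 with the strict filter. List calls lost were 1 with pseudocount 0.5, 0 with pseudocount 5, 0 without a filter, 9 with the strict filter, 2 with equal totals, 1 with upper quartile scaling, 5 with array weights, 0 with robust fitting, 4 with edgeR values and 4 with DESeq2 values. With the dopamine neuron covariate 24 list calls were lost and 1 reversed, and with the oligodendrocyte covariate 29 were lost and 4 reversed.

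Counts of genes past the threshold moved as follows. DESeq2 on recovered reads called 35 for Setd7 without defeat, 85 for defeat with GFP, 6 for Setd7 after defeat, 7 for defeat with Setd7, 1 for the interaction, 26 for both together, 7 for Setd7 averaged over defeat, 8 for defeat averaged over virus and 17 for sex. At unadjusted p under 0.05 the counts in that order were 1423, 1642, 862, 459, 880, 1473, 1265, 919 and 687, and 531 for the Setd7 effect by sex. Without a filter 1 gene passed in Setd7 after defeat and 1 in defeat with Setd7, in both Olfr706 (2.91, adjusted p = 0.0297). With only the groups compared 2 passed in Setd7 after defeat, Cd74 (2.57, adjusted p = 0.0066) and Setd7 (6.56e-05), and 1 in both together, Setd7 (2.96, adjusted p = 0.00813). For Setd7 averaged over defeat 0 passed with robust fitting (Setd7 2.81 as before, adjusted p = 0.632), 0 with the dopamine neuron covariate (Setd7 2.88, 0.0659) and 0 without the 3 libraries with low dopamine neuron genes (Setd7 2.89, 0.190). Without the 2 libraries with high interferon genes 1 passed for Setd7 without defeat, 1 for Setd7 after defeat and 1 for both together, in each case Setd7.

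Values that changed sign: Setd7 in defeat averaged over virus was −0.00149 with array weights and −0.00524 with the oligodendrocyte covariate. Dopamine neuron genes in defeat averaged over virus were −0.000370 with the dopamine neuron covariate, which by construction removes what these genes share. They were −0.00241 with the oligodendrocyte covariate. With the oligodendrocyte covariate, which by construction removes what these genes share, oligodendrocyte genes were −0.0272 for defeat with GFP, −0.0153 for defeat with Setd7 and −0.00298 for Setd7 averaged over defeat. Without the 3 libraries with low dopamine neuron genes Setd7 was 0.3305 for defeat with GFP and −0.000447 in the interaction, oligodendrocyte genes −0.00776 for Setd7 without defeat, clock genes 0.0595 for defeat with GFP and 0.0342 for defeat averaged over virus, ion channels 0.00350 for both together, oxidative phosphorylation −0.0619 for the Setd7 effect by sex, and the correlation of the Setd7 effects without and after defeat −0.0170. Without the 2 libraries with high interferon genes interferon genes were −0.0863 for Setd7 without defeat and 0.00586 for sex, microglia −0.0634 for Setd7 without defeat, meningeal genes −0.0149 for defeat with Setd7, −0.130 for both together, −0.0447 for Setd7 averaged over defeat and −0.144 for defeat averaged over virus, receptors 0.00640 for both together and ribosomal genes −0.00530 for the Setd7 effect by sex.

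The number of the 8 comparisons between groups in which a list is called was 0 with an estimated correlation for the 16 lists called at all (dopamine neuron, GABA neuron, oligodendrocyte, precursor, microglia, endothelial, meningeal, blood, interferon, reactive glia, receptors, ion channels, oxidative phosphorylation, ribosomal, heat shock and clock). With fry it was 2 for ribosomal genes and 0 for the other 15. With both DESeq2 and edgeR it was 1 for choroid plexus, 3 for excitatory neurons and 1 for neuropeptides, each 0 in the planned test. With array weights it was 3 for GABA neurons, 1 for astrocytes, 5 for receptors, 2 for excitatory neurons and 1 for other chromatin regulators. With the dopamine neuron covariate it was 2 for GABA neurons, 0 for dopamine neurons, 0 for receptors, 3 for immediate early genes, 2 for interferon, 0 for ion channels, 1 for microglia, 1 for neuropeptides, 1 for precursors and 1 for reactive glia. With the oligodendrocyte covariate it was 0 for blood, 4 for choroid plexus, 1 for receptors, 2 for immediate early genes, 1 for ion channels, 2 for microglia, 2 for neuropeptides, 0 for oligodendrocytes, 0 for precursors and 3 for oxidative phosphorylation. Equal totals gave 2 for neuropeptides and 2 for other chromatin regulators, no filter 1 for astrocytes, no sex term 1 for astrocytes and 1 for other chromatin regulators, the strict filter 0 for blood and 1 for other chromatin regulators, and upper quartile scaling 1 for other chromatin regulators. Without the 2 libraries with high interferon genes it was 0 for GABA neurons, 0 for endothelial genes, 1 for glucocorticoid response, 0 for receptors, 0 for ion channels, 0 for meningeal genes, 5 for precursors and 0 for reactive glia. Without the 3 libraries with low dopamine neuron genes it was 1 for blood, 2 for clock, 0 for dopamine neurons, 2 for glucocorticoid response, 0 for receptors, 2 for interferon, 0 for ion channels, 1 for microglia, 2 for oligodendrocytes, 0 for precursors and 1 for reactive glia.

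Leaving out each library in turn gave 0 to 4 genes past the threshold for Setd7 without defeat (4 without GFP control replicate 1: Adcy1 −0.83, Avpr1a 1.75, Celf6 0.94 and Scn9a 0.91), 0 to 23 for Setd7 after defeat, 0 to 18 for defeat with Setd7, 0 to 3 for the interaction, 0 to 10 for both together, 1 to 3 for Setd7 averaged over defeat, 0 to 4 for defeat averaged over virus and 0 to 1 for the Setd7 effect by sex (Tcf7l2 2.13 without GFP defeat replicate 3). The upper ends for Setd7 after defeat and the next 5 ranges come without Setd7 defeat replicate 2, with 3 in the interaction (Fn1 1.57, Slc22a8 1.80, Thbd 2.12), 3 for Setd7 averaged over defeat (Fn1 0.83, Prg4 2.29, Thbd 1.06) and 4 for defeat averaged over virus (Col6a2 1.33, Fn1 0.75, Prg4 1.94, Thbd 0.93). The genes in the last 2 sentences were chosen after their values were seen. Setd7 ranged from −0.185 to 0.845 for defeat with Setd7, −0.00968 to 1.09 in the interaction and −0.213 to 0.302 for defeat averaged over virus. List medians with a change of sign ranged as follows: interferon −0.104 to 1.12 for Setd7 without defeat, −0.183 to 1.34 for Setd7 after defeat, −0.0857 to 1.65 for both together, −0.578 to 0.127 for sex and −1.21 to 0.356 for the Setd7 effect by sex; microglia −0.0892 to 0.574 for Setd7 without defeat; meningeal genes −0.125 to 2.15 for both together and −0.105 to 1.01 for defeat averaged over virus; oxidative phosphorylation −0.0181 to 0.155 for defeat with GFP, −0.158 to 0.000850 in the interaction and −0.0176 to 0.0712 for defeat averaged over virus; receptors −0.247 to 0.00710 for both together. The number of comparisons with a list call ranged over 0 to 4 for GABA neurons (1 with all libraries), 0 to 4 for excitatory neurons (0), 1 to 6 for precursors (3), 0 to 1 for astrocytes (0), 1 to 6 for microglia (4), 0 to 6 for endothelial genes (6), 0 to 8 for meningeal genes (6), 0 to 4 for choroid plexus (0), 0 to 4 for blood (3), 0 to 2 for immediate early genes (0), 0 to 2 for glucocorticoid response (0), 0 to 5 for histone H3 lysine 4 methylation (0), 0 to 5 for other chromatin regulators (0), 0 to 5 for reactive glia (3), 1 to 6 for receptors (3), 1 to 5 for ion channels (3), 0 to 1 for synaptic genes (0), 0 to 2 for neuropeptides (0), 0 to 6 for oxidative phosphorylation (6) and 0 to 1 for p53 targets (0). It was 6 to 7 for dopamine neurons (6), 4 to 7 for oligodendrocytes (6), 3 to 6 for interferon (4), 6 to 7 for ribosomal genes (6), 6 to 8 for heat shock (7) and 5 to 7 for clock (6), and 0 throughout for neighbouring nuclei and perineuronal nets.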

Other observations

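Which tests were chosen after the result was seen: the regional marker lists, and the single genes named here.

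Several genes mark tissue next to the VTA in single libraries. Lhx9, a factor of developing thalamic neurons, read 549 and 1444 in GFP control replicates 2 and 3 and 421 in GFP defeat replicate 4. The other 10 libraries read 35.4 to 150. Prkcd and Gbx2, of thalamic neurons, read 4956 and 656 in GFP control replicate 2 and 1410 and 463 in GFP defeat replicate 4, with Prkcd at 211 to 476 in the remaining libraries. GFP control replicate 3 had the highest mean of pons and hindbrain markers, 7.56 against 2.79 to 5.57 elsewhere, with 237 counts of Hoxb3. Nkx2-1, of the hypothalamus, read 454 in GFP defeat replicate 1 and 578 in Setd7 control replicate 3. Pituitary Prl and Gh read 460 and 183 in GFP defeat replicate 2, and 328 and 157 in Setd7 defeat replicate 1.

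Among the 57 genes that DESeq2 called lower after defeat with GFP, where limma and edgeR called 0 (1642 at unadjusted p under 0.05 by limma), were Mir124a-1hg (−1.13, adjusted p = 1.0e-05), Mirg (−0.88, 0.02), Snhg11 (−1.01, 0.0385), Rbmx (−0.39, 0.0351), Leng8 (−0.80) and Tial1 (−0.29). Cd74, of antigen presentation, read 8725 in Setd7 control replicate 4 and 902 and 623 in Setd7 defeat. Setd7 defeat replicate 1, with meningeal genes at 10.32, also had the highest endothelial mean (10.09) and 1337 counts of Col1a2.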
